A study of Drosophila melanogaster with 2 samples.

How the data were processed

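Peak lists from 2 biological replicates of chromatin immunoprecipitation sequencing on whole Drosophila melanogaster embryos were analysed. Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. Both replicates formed 1 group, named from the labels, with the replicate numbers 1 and 3 taken from the same labels. They are separate biological samples of the same transgenic line. The free-text description of each sample speaks of an input control, which goes against its assay title and antibody field. The samples were treated here as immunoprecipitations because these 2 labels say so.

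The authors deposited 4 lists in narrowPeak format on the dm6 build. Per the file descriptions deposited with the samples, each replicate's list came from that replicate's alignment together with a control, and the pooled list came from both alignments together with the same control. The control itself was not analysed here. Each of these 3 lists held 30000 peaks. The IDR list was made from the replicate and pooled lists, and its 5744 rows were identical to the 5744 pooled rows with the highest signal. The aligner, its treatment of reads from near-identical sequences, the peak caller and the IDR threshold are not given in the sources used here. The signal of a peak is the authors' deposited value for that peak within its list, and lists were not scaled to each other, so signals were ranked or described within a list. The deposited −log10 q-value was capped, all 5744 IDR peaks stood at the cap of 4.09, and it was not used to rank peaks. The deposited offset of the summit from the peak start gave the summit, and was set to the last base of the peak where it pointed beyond its end (4 IDR peaks). The lists give no read counts, so depth per sample is unknown and cannot be weighed. A list with a fixed length also holds background, and a strong signal at an accessible promoter can arise in any immunoprecipitation.

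Overlapping IDR peaks were merged where they shared at least 1 bp, and the region kept the summit and signal of its strongest peak. Of the 5206 regions, 4694 came from 1 peak and 512 from more. Sequence came from the RefSeq copy of the dm6 assembly and genes from the Ensembl release 115 annotation in the same coordinates, and 0 peaks lay beyond the end of an arm. Regions were linked to 13945 protein-coding genes with 19607 TSS positions on arms 2L, 2R, 3L, 3R, 4 and X. Other contigs were left out. A summit within 1000 bp of a TSS was called a promoter summit. A region near TSSs of several genes counted for each of them, which concerned 1212 regions against 2158 near 1 gene. Other summits were assigned in the order 5′ untranslated region, coding exon, 3′ untranslated region, intron and intergenic.

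Comparison peaks were 5206 regions drawn with a fixed seed from 14878 merged pooled peaks that lay over 1000 bp from any IDR peak. Their median signal was 64.8. Replicate overlap was compared with 1000 circular shifts per arm, and the promoter share and genomic classes with 1000 random placements. Alternative settings used 100 shifts, 100 placements for the promoter share and 1000 for genomic classes. Counts over the arms were compared with a larger number of placements. Words were sought on either strand within 100 bp of the summit and compared with a window 500 bp to the left or right, drawn at random, by the exact McNemar test. Medians were compared by two-sided permutation tests with 100000 resamples. The window over the E(spl) complex, with 5000 bp on each side, was compared with 10000 random windows by a one-sided test. Gene lists were compared with all other genes by two-sided Fisher's exact tests. These tests take genes as independent, although neighbouring genes can share a region. Benjamini-Hochberg adjustment ran over the 24 gene lists, the 16 words, or the 13 lists with at least 5 genes that had a region, and 0.05 was the threshold. All p-values are over regions or genes within this group. They do not measure variation between embryo collections, for which 2 replicates allow no test.

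Gene lists, words, tests and the rule for naming genes were fixed before the data were examined. The lists were the E(spl) complex, other bHLH-Orange repressors with Groucho, proneural and other bHLH factors, the Notch, EGFR, Wnt and Dpp pathways, the Bearded family, neuroblast and temporal factors, pan-neuronal genes, glia, segmentation, Hox, mesoderm and muscle regulators, muscle structure, trachea and epidermis, gut, haemocytes and fat body, germ line, cell cycle, ribosomal proteins, chemosensory receptors, eggshell and yolk, and trypsins. Some genes belong to several lists. The rule named the 20 strongest regions by the nearest TSS, every E(spl) complex gene, and the 4 genes of highest signal in each other list past the threshold. For each list not past it the rule named the gene of highest signal, and for each replicate the 5 strongest peaks among its 5744 strongest with no overlap in the other's 5744 strongest. Alternatives changed the overlap rule, merging, list threshold, TSS window, background, word window and gene matching, and left out each replicate in turn by using the 5744 strongest peaks of the other.

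Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0. The procedures were tested on simulated data. In 5206 windows with CACGTG planted in 4.82%, the excess recovered was 4.57% and 0 other words were called. These windows were shifted away from pooled-list summits, so they do not test words that differ between real summits and their flanks. Among 5181 regions with 48.4% copied into a second list, 100% of copies and 2.36% of randomly placed regions were found. Of 100 simulated lists of 25 genes with regions at 60% of genes against 28% elsewhere, 50 were called, and 0 of 100 lists at the background rate were. A list of this size can therefore hide a sizeable difference. In 200 comparisons of medians without a difference, 6 passed the threshold.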

Results

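Chromatin immunoprecipitation followed by sequencing was carried out on whole embryos of Drosophila melanogaster, of both sexes, collected from 0 to 24 hours of development. The embryos came from a transgenic line that expresses E(spl)mβ-HLH with GFP fused to its C terminus. E(spl)mβ-HLH is a basic helix-loop-helix repressor of the Hairy/E(spl) family, and its gene lies in the Enhancer of split complex, whose genes respond to Notch signalling. The series held 1 group of 2 biological replicates, numbered 1 and 3 in the labels. No sample of another group was analysed here, so no comparison between conditions was made. The free-text description of both samples calls them an input control, whereas the assay title and the antibody field describe an immunoprecipitation of the tagged factor. All values below carry this uncertainty of the labels. The lists gave no read counts, and the depth of each sample is unknown. Intervals on shares are 95% Wilson intervals, which cover counting error only.

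The first question was how far the replicates shared their strongest peaks. The authors' reproducible list, thresholded on the irreproducible discovery rate (IDR), held 5744 peaks, which merged into 5206 regions on arms 2L, 2R, 3L, 3R, 4 and X. These regions had a median width of 382 bp and covered 1.53% of the 6 arms. Of the 5744 strongest peaks of replicate 1, 80.6% (79.5 to 81.6%) overlapped one of the 5744 strongest of replicate 3. The reverse share was 79.7% (78.6 to 80.7%). Circular shifts of the peaks along each arm gave 3.01% on average and at most 4.84% in 1000 shifts. Across the 4120 pairs of overlapping peaks, signal had a Spearman rho of 0.790 between replicates, and log2 signal had a Pearson r of 0.890. Peaks are not independent replicates, so no p-value was attached to these coefficients. In 4056 regions, or 77.9%, both replicates had a peak among their 5744 strongest.

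**Figure D1:**
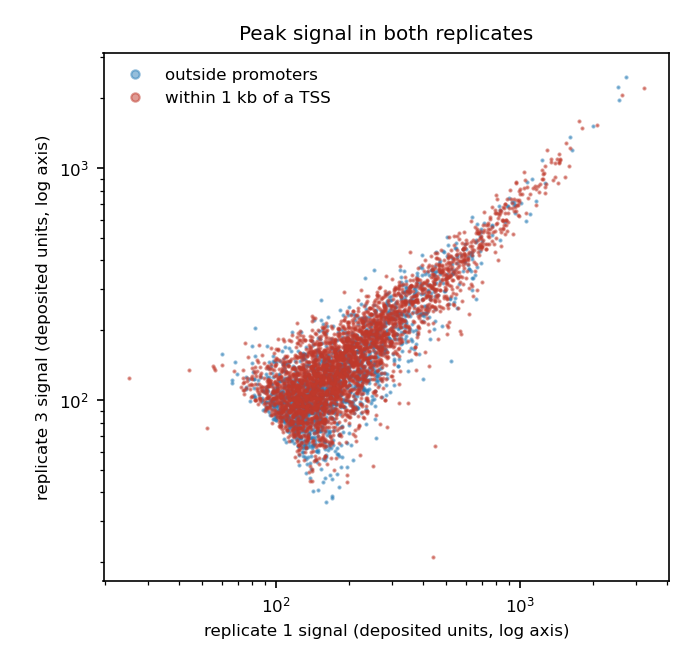
Signal in replicate 3 against signal in replicate 1, in deposited units on log axes, for the 5126 regions that have a peak in both full lists. Each point is a region, in red for the 3314 within 1 kb of a transcription start site and in blue for the 1812 elsewhere; signals rise together, and the scales of the axes are not matched between replicates.

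Strong peaks listed for 1 replicate and missing from the other's list were few. Among the 1000 strongest peaks of replicate 1, 979 overlapped one of the 5744 strongest of replicate 3, 3 overlapped a weaker peak and 18 overlapped no listed peak. For the 1000 strongest of replicate 3 the corresponding counts in replicate 1 were 990, 1 and 9. The 5 strongest replicate 1 peaks without a counterpart lay nearest to fkh, a forkhead transcription factor of the gut, and to sp3, fws, Hr3 and CG8202. The fkh peak (3R 28585195 to 28585671) ranked 79 in replicate 1, with a signal of 949.1. The 5 strongest of replicate 3 without a counterpart lay nearest to CG32022, CG5098, the ribosomal protein gene RpL34a, Cib2 and the nuclear receptor gene ftz-f1. They had signals from 332.3 (ftz-f1) to 492.7 (CG32022). None of these 10 peaks overlapped any of the 30000 peaks listed for the other replicate.

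The strongest region of the reproducible list lay at the tagged gene itself. It spanned 3R 26005796 to 26007488 (dm6), and its summit was 101 bp from the transcription start site (TSS) of E(spl)mbeta-HLH. Its pooled signal was 5401, against a median of 299.1 over all regions. It ranked 1 in replicate 1 and 3 in replicate 3. The region ranked 10, with a signal of 2976, lay between E(spl)mbeta-HLH and E(spl)malpha-BFM, at 3R 26007948 to 26009527 in intergenic sequence. Altogether 9 regions fell within 5 kb of the E(spl) complex (3R 25992621 to 26046008). Windows of this length placed at random on 3R held 1.99 on average (10000 windows, one-sided permutation p = 0.0326, maximum 24).

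Within the complex the regions were unevenly placed. A block of 8 regions reached from 3R 26002469 to 26021436, with the tagged gene near its left end. Signals in the block ran from 310.5 to 5401. The ninth region (3R 26042311 to 26042669, signal 760.5) lay at a TSS of gro, which encodes the co-repressor Groucho and adjoins the complex. Of the 12 listed complex genes, 3 had a region summit within 1 kb of a TSS. These were E(spl)mbeta-HLH, E(spl)malpha-BFM with a signal of 403.5, and Kaz-m1 (E(spl)m1) with a signal of 310.5. The other 9 had none, namely E(spl)mdelta-HLH, E(spl)mgamma-HLH, E(spl)m2-BFM, E(spl)m3-HLH, E(spl)m4-BFM, E(spl)m5-HLH, E(spl)m6-BFM, E(spl)m7-HLH and E(spl)m8-HLH. The share of 25% (8.89 to 53.2%) was not separated from that of other genes by Fisher's exact test (27.8%, adjusted p = 1). The 3 genes with a region lie in the block around the tagged gene, and without the block the share was 0. With a window of 5 kb around the TSS it was 8 of 12 (66.7% against 45.8%; Fisher's exact test, adjusted p = 0.351), and without replicate 1 it was 4 of 12 (Fisher's exact test, adjusted p = 0.82).

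**Figure D2:**
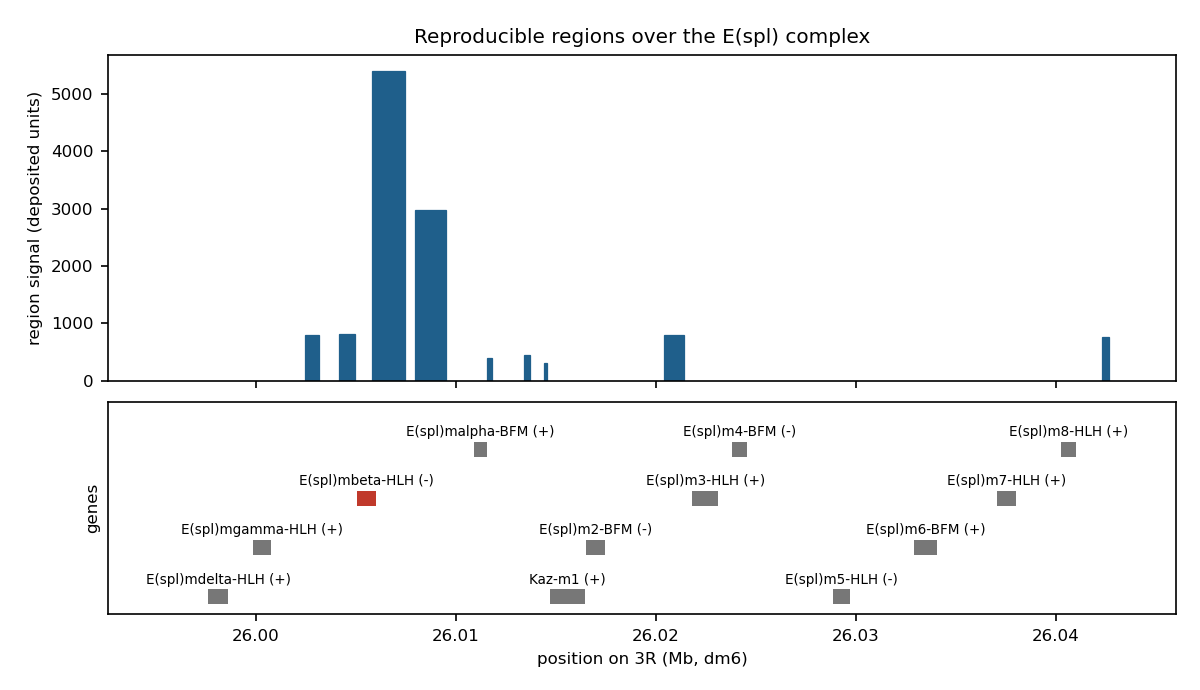
The E(spl) complex on 3R, with position in Mb (dm6) on the x axis. The upper panel gives the pooled signal of each of the 9 reproducible regions as a bar as wide as the region; the lower panel gives the 12 listed genes with their strands, with the tagged gene in red, overlapping the tallest bar (5401), while the next tallest (2976) lies between it and E(spl)malpha-BFM.

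Beyond the tagged gene, the 20 strongest regions named genes of varied function. Signals in this set ran from 2481 to 5401, and each of its regions ranked 22 or better in replicate 1 and 25 or better in replicate 3. The regions after the first lay nearest to CG11050 (5177, intron) and to cbt, a zinc-finger transcription factor gene (4740, intron). The classes refer to any protein-coding gene and not only the gene named. The summit named after cbt lay within the span of ush (2L 476220 to 540560). Next came Ugalt, a UDP-galactose transporter gene (4660, promoter), CG4004 (4510, intergenic) and CG14100 (3610, promoter). The region nearest to Trl, which encodes GAGA factor, was intronic and had a signal of 3513. Promoter regions at Gapdh2, a glycolytic enzyme gene, and at Hsp83, the Hsp90 chaperone gene, had signals of 3326 and 3268. The other region of the E(spl) block in this set was named after E(spl)malpha-BFM. The rest lay nearest to Lk6, CG32772, mRpL41, jp, shn, CG11309, CG13390, Art3, CG15771 and CG9663. Of the 20 summits, 14 lay within 1 kb of a TSS, and 0 had CACGTG or CACGCG within 100 bp. The share with either word was 11.5% in the 1041 strongest regions and 11.7% in all regions, and the difference was not tested.

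The regions were concentrated at promoters. Of the 5206 summits, 3370 lay within 1 kb of a TSS of a protein-coding gene, or 64.7% (63.4 to 66.0%). Comparison peaks, taken from weaker parts of the pooled list over 1 kb from any reproducible peak, had 23.2% (22.1 to 24.4%; n = 5206). The odds ratio was 6.08, and the p-value of Fisher's exact test was too small for the software to represent. Leaving out peaks within 1 kb of reproducible ones removes many promoters from the comparison set. Its promoter share is therefore lowered by construction, and the odds ratio and p-value are partly set by that choice. Random placement within the arms gave 20.4% on average and at most 22.4% in 1000 placements (permutation p = 0.001, the smallest these placements can give). As shares of all summits, the other classes were therefore small, with 25.2% intronic (36.3% at random), 8.43% intergenic (28.3%), 0.980% in 3′ untranslated regions, 0.327% in 5′ untranslated regions and 0.288% in coding exons. Among the 1836 summits outside promoters, a set chosen after seeing these shares, introns held 71.6% (69.5 to 73.6%) against 45.5% of random positions outside promoters. Intergenic sequence held 23.9% of them against 35.6%, coding exons 0.817% against 13.5%, and 3′ untranslated regions 2.78% against 4.81% (permutation p = 0.001 for each of these 4 classes). The share in 5′ untranslated regions was 0.926% against 0.575% (17 summits, permutation p = 0.005). Comparison peaks outside promoters departed from random positions in the same directions, with 63.8% in introns, 29.6% intergenic, 2.43% in coding exons, 3.55% in 3′ and 0.650% in 5′ untranslated regions, so much of the departure is not particular to the reproducible regions.

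Densities were similar on the large arms and lower on the small chromosome 4. The X carried 38.0 regions per Mb, and 2L, 2R, 3L and 3R carried 40.1, 42.0, 38.8 and 37.3. Chromosome 4 carried 13.4 per Mb, from 18 regions (exact Poisson interval 7.91 to 21.1). Counts over the arms departed from arm length (chi-square 32.2, placement p = 1e-04, the smallest these placements can give). The density on the X relative to the autosomes was 0.973.

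Genes of the ribosome carried regions far more often than other genes. A region summit lay within 1 kb of a TSS in 71 of 88 ribosomal protein genes, or 80.7% (71.2 to 87.6%), against 27.5% of other genes (Fisher's exact test, adjusted p = 1.47e-23 over 24 lists). The strongest were RpS27 (signal 2096, 12 bp from the TSS), RpL7 (1974), RpL11 (1787) and RpS4 (1715). Signal at these promoters was also higher, with a median of 777.9 over 71 genes against 327.7 at other genes with a region (permutation test, adjusted p = 0.00013 over 13 lists). It was the only list past the threshold in that test. Overall 3877 of 13945 protein-coding genes, or 27.8%, had such a region.

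Gene groups with restricted expression in late or adult tissues carried regions less often. Odorant, gustatory and ionotropic receptor genes had a region in 3 of 179 cases, or 1.68% (Fisher's exact test, adjusted p = 3.11e-20). These were Gr63a (signal 243.6), Gr97a (232.2) and Ir60e (208.3). Eggshell and yolk genes had 0 of 20, with an upper limit of 16.1% (Fisher's exact test, adjusted p = 0.0139). Trypsin-type digestive protease genes had 1 of 27, zetaTry with a signal of 193.9 (Fisher's exact test, adjusted p = 0.0139). The calls of the last 2 groups depended on the processing. The eggshell call was lost in 3 of 9 alternatives (adjusted p up to 0.171) and the trypsin call in 6 of 9 (up to 0.441). The tests and intervals in this paragraph take genes as independent. Genes of a family that lie side by side can carry or lack regions together, so the p-values can be too small and the intervals too narrow.

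Lists of signalling and developmental genes did not pass the threshold. Regions lay at 8 of 24 Notch pathway genes, led by the protease gene kuz (signal 845.0), and at 4 of 7 other bHLH-Orange repressor genes and gro. For these adjusted p was 0.705 and 0.238. The EGFR list had 11 of 25, led by the ligand gene spi (944.9), the Dpp list 11 of 27, led by shn (2597), and the Wnt list 8 of 23, led by the kinase gene sgg (1011). Adjusted p was 0.209 for EGFR, 0.273 for Dpp and 0.705 for Wnt. Proneural and other bHLH genes had 6 of 28, led by crp (424.7; Fisher's exact test, adjusted p = 0.705). The 4 Bearded family genes outside the complex and the 8 Hox genes had 0, with adjusted p of 0.705 and 0.254, and these counts allow shares of up to 49.0% and 32.4%.

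Tissue lists gave the same outcome. Pan-neuronal genes had 6 of 20 (elav, an RNA-binding protein gene of neurons, 1934; Fisher's exact test, adjusted p = 0.891), and glial genes had 7 of 14 (moody, 1417; adjusted p = 0.209). Counts were 6 of 17 for gut (fkh, 1458), 7 of 23 for trachea and epidermis (crb, 451.5) and 3 of 16 for haemocytes and fat body (ush, 522.2). For these 3 lists adjusted p was 0.705, 0.891 and 0.705. Muscle structural genes had 5 of 20 (Msp300, 1148; Fisher's exact test, adjusted p = 1), germ line and maternal genes 6 of 17 (bgcn, 857.6; adjusted p = 0.705) and cell cycle genes 10 of 28 (dup, 563.0; adjusted p = 0.705). The fkh region had no listed peak in replicate 3.

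Segmentation, neuroblast and mesoderm regulator lists did not pass the threshold either. Segmentation genes had 3 of 31 (hry, the hairy gene, 519.8), neuroblast and temporal factor genes 3 of 26 (brat, 1089) and mesoderm regulators 3 of 27 (Mef2, 471.2). Unadjusted p was 0.0255, 0.0783 and 0.0541, and adjusted p was 0.123, 0.209 and 0.209. Under other ways of linking or matching genes, these lists fell below other genes past the threshold in 2, 3 and 1 of 9 alternatives, with lowest adjusted p of 0.00145, 0.0016 and 0.0276. Hox genes passed it in 1, with a window of 5 kb around the TSS (Fisher's exact test, adjusted p = 0.0373).

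**Figure D3:**
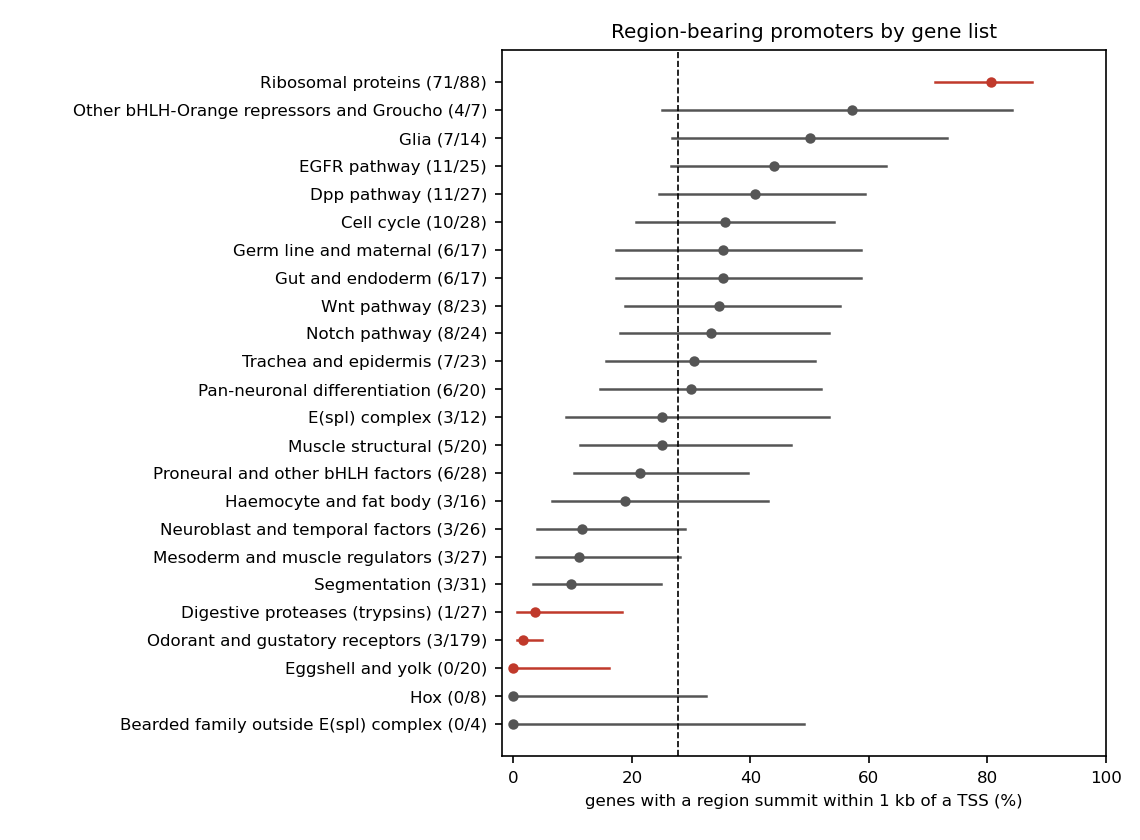
Share of genes in each of the 24 lists with a region summit within 1 kb of a TSS, in percent, with 95% Wilson intervals as lines and the counts beside the names. The dashed line is the share over all protein-coding genes (27.8%); red marks the 4 lists past an adjusted p of 0.05, of which ribosomal proteins lie above it and the other 3 below it.

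CACGTG and CACGCG, the words set beforehand for E(spl) proteins, were more frequent at summits than beside them. The forms of CACNAG, the N-box, which E(spl) proteins are also known to bind, did not agree in the main setting. There CACTAG was higher, CACCAG lower, and CACGAG and CACAAG did not pass (values below). CACGAG was higher past the threshold with windows of 50 bp (log2 ratio 0.41, exact McNemar test, adjusted p = 0.0447) and 250 bp (0.20, adjusted p = 0.0241). It passed in no other alternative. CACGTG lay within 100 bp of 4.01% of summits (3.51 to 4.58%) and in 2.44% of windows 500 bp away, a log2 ratio of 0.72 (exact McNemar test, adjusted p = 1.98e-05 over 16 words). CACGCG lay at 8.16% of summits (7.45 to 8.94%) and in 5.21% of those windows, a log2 ratio of 0.65 (exact McNemar test, adjusted p = 7.87e-09). Among all hexamers, with strands merged, they ranked 8 and 14 by this ratio. Against comparison peaks the excess of CACGTG fell to a log2 ratio of 0.27 and did not pass Fisher's exact test (adjusted p = 0.136). CACGCG kept a log2 ratio of 0.62 there and passed Fisher's exact test (adjusted p = 3.37e-08). The ranks of CACGTG and CACGCG became 310 and 31. Most regions lacked both words, which were found at 611 of 5206 summits, or 11.7%.

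Words of general promoter factors showed larger ratios. TATCGATA, the word of DREF, lay at 3.98% of summits against 0.711% of flanks (log2 ratio 2.47, exact McNemar test, adjusted p = 3.16e-29). GGTCACACT, the core of the M1BP word, lay at 2.07% against 0.346% (log2 ratio 2.55, exact McNemar test, adjusted p = 6.29e-16). The top hexamers were CGATAG, ACACTG and TATCGA, with log2 ratios of 1.29, 1.16 and 0.95. CACTAG (5.40% against 3.50%), CAGCTG (12.3% against 8.66%) and GAGAGAG, the word of GAGA factor (6.09% against 4.28%), were also higher. CACCAG, CAGGTG, CAAATG, CATCTG and CAGGTAG, the word of Zelda, were lower, with log2 ratios of -0.44, -0.38, -0.16, -0.35 and -0.99. Against comparison peaks 6 words were higher, GGTCACACT with a log2 ratio of 1.29, and only CAAATG stayed lower. By Fisher's exact test CACCAG (adjusted p = 0.179), CAGGTG (0.945) and CATCTG (0.381) no longer passed, nor did CAGGTAG, which turned to a log2 ratio of 0.20 (0.767). Comparison peaks lay at promoters less often (23.2% against 64.7%). Words common at promoters, such as GGTCACACT and TATCGATA, can differ for that reason alone, which these ratios do not separate. CACGAG, CACAAG, CATATG and YGTGRGAA, the word of Su(H), did not pass the exact McNemar test in the main setting (adjusted p from 0.324 to 0.944). Outside promoters, of the words higher over all summits only CACGTG and CACGCG passed against flanks. They did so narrowly (exact McNemar test, adjusted p = 0.0359 and 0.0373). TATCGATA was too rare to compare there (4 summit windows against 6 flank windows; exact McNemar test, adjusted p = 1).

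**Figure D4:**
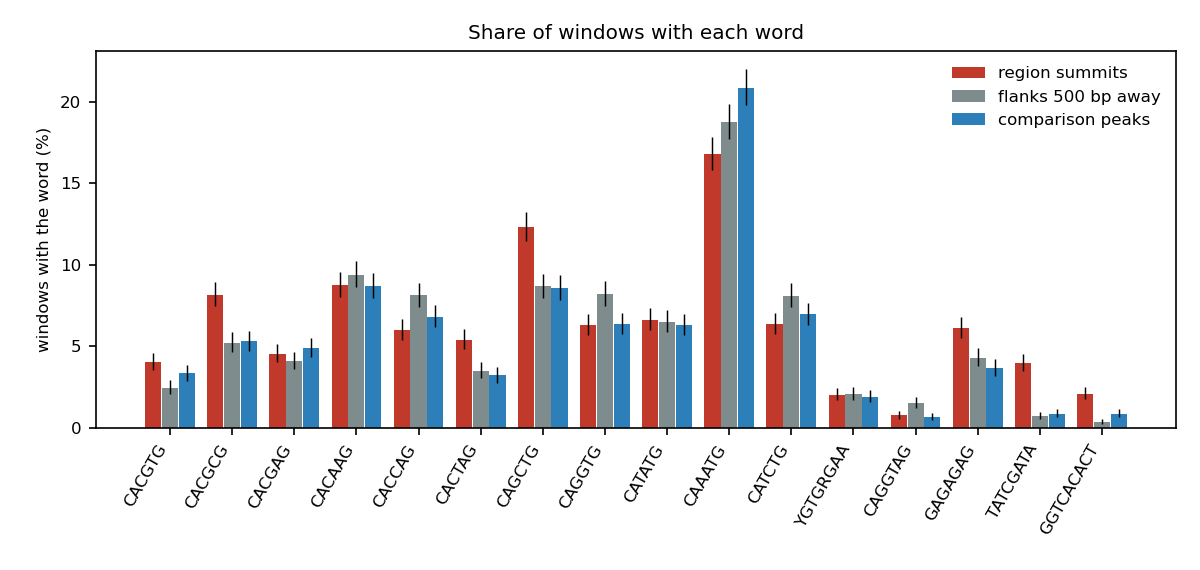
Percentage of windows, reaching 100 bp to each side of their centre, with each of 16 words, at region summits (red), at flanks 500 bp away (grey) and at comparison peaks (blue). Error bars are 95% Wilson intervals, and each set holds 5206 windows; TATCGATA has 3.98% at summits and 0.711% at flanks.

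Where CACGTG or CACGCG occurred, it lay nearer to summits than to the centres of flanking windows. The median distance within 250 bp was 101.5 bp in 1243 regions and 125.5 bp in 988 flanks (permutation test, p = 5e-05). Within 100 bp the medians were 41.5 and 46.5 bp and the permutation test did not pass (p = 0.238), and neither did it outside promoters (92.5 against 109.5 bp, p = 0.129). At promoters the difference had the same size and passed (104.5 against 121.5 bp, permutation p = 0.0294), as did the differences without replicate 1 (permutation p = 0.0223) and without replicate 3 (permutation p = 0.0182). With replicate 1 or 3 left out the difference was -13 bp in place of -24 bp. The summit medians there were 103.5 and 102.5 bp, and the flank medians 116.5 and 115.5 bp, so the change lay mainly in the flanks. At promoters and elsewhere the flank medians (121.5 and 109.5 bp) were both below 125.5 bp, so flank draws differed between settings. The size of the main difference may therefore depend on the draw, which was not tested. Signal was not separated by the presence of these words in the main setting. Its median was 306.2 in 611 regions with a word and 298.5 in 4595 without (permutation test, p = 0.314). Within promoters the medians were 314.4 and 309.8 (permutation p = 0.635), and elsewhere 289.4 and 276.8 (p = 0.352). Without replicate 3 the difference elsewhere was 16.8 and passed (permutation p = 0.0263). Over all regions, the difference passed narrowly with words sought within 250 bp (11.6, permutation p = 0.0495) and without replicate 1 (6.45, permutation p = 0.0484), but was -0.20 without replicate 3 (permutation p = 0.958).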

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

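The nearest-TSS linking of regions, the removal of the block around the tagged gene, the words and their distances at promoters alone and the classes of summits outside promoters were chosen after seeing the data. Of 440 alternative values over 61 results, 349 kept their direction and their side of the threshold or stayed within the set tolerance. The promoter excess, the CACGCG excess over flanks, the ribosomal protein and receptor calls and the count of regions over the E(spl) complex kept theirs in each alternative run. Replicate rho was 0.806 over all overlapping peaks and 0.741 over those that overlap an IDR peak, and the stronger part of the IDR list gave 2695 regions, fewer by construction. Against comparison peaks the log2 ratio of CACGTG was 0.27 and the hexamer ranks were 310 and 31, and CAGGTAG turned to 0.20, CACGAG to -0.10, CACAAG to 0.00953 and YGTGRGAA to 0.10, none past the threshold. Outside promoters 2 words were higher in place of 7. There the log2 ratios of CAGCTG and GAGAGAG fell to 0.07 and 0.02 and TATCGATA turned to -0.53 (4 windows against 6; exact McNemar test, adjusted p = 1) and YGTGRGAA to 0.077 (at promoters 0.0215), while CACGTG and CACGCG had 0.83 and 0.52 in the same 1836 regions. As a share of summits outside promoters introns (71.6%) and 5′ untranslated regions (0.926%) turned from below to above random placement, since promoter summits no longer counted. With a window of 50 bp GAGAGAG turned to -0.024 (exact McNemar test, adjusted p = 0.948). With 250 bp CATATG turned to -0.11 and YGTGRGAA to 0.0796, with the other flanks CACGAG to -0.14 and without replicate 3 CATATG to -0.0167 (0.0208 without replicate 1), none past the threshold. By the exact McNemar test CACGAG gained a call with 50 bp (adjusted p = 0.0447) and 250 bp (0.0241). Calls were lost for CAGGTG with 50 bp (0.0559) and for CAAATG (0.606) and CAGGTAG (0.134) with 250 bp. With the stronger part of the IDR list GAGAGAG (0.0923) and CAGGTAG (0.0641) lost theirs. The distance of CACGTG or CACGCG was not separated from flanks within 100 bp (41.5 bp) or outside promoters (92.5 bp). It was separated at promoters (104.5 bp) and without either replicate (103.5 and 102.5 bp), where the difference was -13 bp in place of -24. That change lay mainly in the flank medians (116.5 and 115.5 bp in place of 125.5 bp). Signal with against without these words differed by 11.6 with a window of 250 bp (permutation p = 0.0495), and by 6.45 without replicate 1 (p = 0.0484) and -0.20 without replicate 3 (p = 0.958), where it was 16.8 outside promoters (p = 0.0263). Within promoters it turned to -4.25 with 50 bp and -7.68 without replicate 3 (5.97 without replicate 1), neither past the threshold. Gene lists past the threshold numbered 2 in place of 4 with the stronger part of the IDR list and 2 with nearest-TSS linking, each of which leaves fewer genes with a region. They numbered 3 without replicate 1, 5 matched on TSS number, 6 with a 5 kb window and 4 in the other alternatives. Some lists turned without passing the threshold before or after. The E(spl) complex turned to above its reference with a 5 kb window (66.7%), without replicate 1 (33.3%) and, at 25%, with both matchings, the stronger part of the IDR list and nearest-TSS linking. Matched on gene length, Notch (33.3%), EGFR (48%), pan-neuronal (45%), trachea (39.1%) and gut (35.3%) turned to below it. So did Notch (37.5%), pan-neuronal (45%), Dpp (44.4%), trachea (39.1%) and gut (41.2%) with 5 kb, and pan-neuronal (30%), trachea (30.4%) and gut (35.3%) matched on TSS number. Pan-neuronal also did with the stronger part (15%), gut without replicate 1 (23.5%) and germ line with nearest-TSS linking (17.6%). Proneural (21.4%) and muscle structure (25%) turned to above with that linking, and muscle structure without replicate 3 (30%, and 20% without replicate 1). Where no construction is named, the cause was not tested. No paired analysis was possible because there was only 1 group. Depth was unknown, so its part in weak or missing peaks could not be weighed.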

Other observations

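Groups of genes outside the fixed lists, chosen by symbol after seeing the data, were tested in the same way. Mitochondrial ribosomal protein genes carried a region in 32 of 73 cases, or 43.8% (33.0 to 55.2%), against 27.7% of other genes (Fisher's exact test, adjusted p = 0.00541 over 6 groups). Cuticle protein genes had 1 of 95 (Fisher's exact test, adjusted p = 1.1e-11), odorant-binding protein genes 1 of 51 (adjusted p = 6.16e-06) and cytochrome P450 genes 12 of 85 (adjusted p = 0.00541). Proteasome subunit genes had 15 of 48 and translation initiation factor genes 16 of 44, and neither passed Fisher's exact test (adjusted p = 0.629 and 0.285). Ranked by signal, the 1041 strongest regions were at promoters in 72.0% and the 1042 weakest in 55.1%, while CACGTG or CACGCG was present in 11.5% and 12.7%.

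In the weighing that follows, the test of transgene copies, the tests of words and their distances at promoters alone, and all tests of missing peaks were chosen after the results were seen. The design has 1 group, so no biological explanation was tested against another condition.

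The block of 8 regions around the tagged gene may come from extra copies of a transgene insert, since the line carries a tagged copy of the gene. The lists were made together with a control, which was not analysed here. Whether that control holds the same insert, and so offsets extra copies, was not examined. Of the 8 complex genes with no TSS in the block, 1 had a pooled-list peak within 1 kb of a TSS, E(spl)m3-HLH beside the right end of the block. That decides nothing about extra copies of a transgene insert, because the block was drawn from the same regions and local binding would give the same. The block had reproducible regions no nearer than 33628 bp to its left and 20874 bp to its right. Signals in the block from 310.5 to 5401 do not exclude a rise of background over the insert, which stays open. Binding at the factor's words was not resolved, with a word in 1 of 8 block regions against 11.7% of all regions (exact binomial p = 1 for binding at CACGTG or CACGCG words in the block). Extra copies and binding of E(spl)mβ-HLH at its own gene therefore stay open, together or alone, and the extent of the insert is not given in the sources used here.

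The regions at promoters might be recovered without the factor's own words, as at accessible promoters in general. In promoter regions CACGTG or CACGCG had a log2 ratio of 0.20 over comparison peaks at promoters (12% against 10.4%, Fisher's exact p = 0.157), while over flanks CACGTG had 0.65 (exact McNemar test, adjusted p = 0.0019) and CACGCG 0.53 (adjusted p = 0.000114). Another 5 words, TATCGATA among them, were also higher over flanks there, so flanks do not separate the factor's words from promoter sequence, and this stays open. Outside promoters the log2 ratio over flanks was 0.64 (exact McNemar p = 2.76e-05), but those regions are not part of the pattern, so that test was wrongly placed to exclude it. The words did not lie detectably nearer to summits there (difference -17.0 bp, permutation p = 0.129). At promoters they did (104.5 against 121.5 bp, permutation p = 0.0294), where accessible promoters in general could give the same, so libraries that are the input controls of the description cannot be told apart from immunoprecipitations by this test. Promoter regions with TATCGATA or GGTCACACT had a median signal lower than the rest (difference -21.7, permutation p = 0.0485), a difference close to the threshold. These exact words therefore did not mark promoter regions of higher signal. Only 301 of 3370 promoter regions had either, and the rest can hold other promoter words. Promoter words as carriers of the signal therefore stay open.

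Strong peaks missing from the other replicate's list, such as the one at fkh, could reflect absent reads or gaps left when a list was made. Ratios of pooled to replicate signal at the missing peaks were tried in 4 forms after the values were seen, the last with a rule added once its outcome was known. None is used here, because signals are not scaled between lists. Whether reads were absent or fewer was therefore not decided. The pooled list lacked 1 of 835 peaks that were among the 1000 strongest of both replicates, near MRP (2L 12721856 to 12722278, chosen after its values were seen), so gaps left when a list was made are a candidate explanation for single missing peaks, and 5 further strong peaks of each replicate were missing from both the other list and the pooled one.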
